A study of Mus musculus with 18 samples.

How the data were processed

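The 18 samples were grouped from the sample labels into 6 groups of 3, iWAT, day 0 cultures and day 7 cultures, each WT and NFIA-Tg. Per the labels' protocols, RNA was extracted with Trizol and RNeasy columns and libraries were made from polyadenylated RNA with a stranded mRNA kit. The submitters' processing notes name STAR 2.7.8a, StringTie 2.1.1 and the mouse genome build mm9, without saying which step each served. The annotation, the strand setting, the treatment of reads that map to several places and the rule for counting are not given in the sources used here. The deposited files give 1 FPKM value (fragments per kilobase of transcript, scaled to the library's total) and a length for each gene, per the file headers. Coordinates are not printed, because the reference genome used here is another build. The iWAT tables list 25209 gene symbols, those of the cultures 24825, and 24338 are shared, and in iWAT 410 entries share 180 symbols and were summed. In the cultures, FPKM times length fell on whole multiples of 1 step for 100% of values within a tolerance of 0.01, so reads per library could be recovered. The iWAT values did not give reads, and precision there can be judged only from the spread between libraries. In the cultures, pairs of replicates differed in their recovered reads by more than counting noise, with a chi-square per degree of freedom of 4.23 to 27.8 over genes with at least 20 reads.

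Tests were run with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with eBayes and a mean-variance trend. Genes needed an FPKM of at least 1 in at least 3 of the fitted samples. P-values were two-sided and Benjamini-Hochberg adjusted over the genes tested, and a gene was called at an adjusted p under 0.05. A fold change on this scale understates the change of low genes. Genotype in iWAT was fitted on 6 samples (4 residual degrees of freedom). Genotype at day 0 and day 7, differentiation in each genotype and the genotype by differentiation contrast came from 1 fit to the 12 culture samples (8 degrees of freedom). The contrast of the genotype effect in iWAT with that at day 7 was fitted on the 6 iWAT and the 6 day 7 samples (8 degrees of freedom). Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 with at least 5 measured genes, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Camera sets a list against the other genes tested, while fry asks whether the genes of a list change by themselves. Counts of called members are given over all genes tested and, where said, adjusted over the list alone (in short, over the list alone). The 26 lists cover mitochondrial and metabolic programmes, inflammation, matrix, markers of other cell types, proliferation, stress and ribosomes. Overlaps of calls were tested with two-sided Fisher's exact tests. The groups, tests, lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names Nfia, Nfib, Nfic, Nfix, Pparg, Ppargc1a, Ucp1, Cidea, Adipoq and Ccl2, the 4 largest increases and 4 largest decreases among called genes with separated groups and a mean of at least 5 FPKM in the higher group (predicted, ribosomal, histone and small RNA genes left out). It adds the 2 called members with the smallest adjusted p of each programme list, or the most abundant member where none is called, and 1 such member of each marker or quality list with a call. The genotype by differentiation contrast takes 1 member of each programme list. Genes named outside the rule are said to be so, and 2 genes that the rule names are not reported here. Genes with near-identical copies, such as Xlr, Xlr3b, Lyz1, Oas1a, Rps4x, Saa3 and Orm1, can share reads and their values are uncertain.

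The gene and list tests were tested on simulated data made from the means and spreads of these groups, with 200 seeded genes and with 1 shifted list of 50 genes. The overlaps, the splits of samples, the voom fit and the tests of explanations were not. Seeded and shifted genes were drawn from those with a mean log2(FPKM + 1) of at least 2. Recovery of changes in lower genes was therefore not tried. For genotype in iWAT, 0 of the 200 were called at a log2 change of 0.5, 148 at 1 and 200 at 2. At day 0 the numbers were 184, 198 and 200, and at day 7 178, 197 and 200. For differentiation in WT they were 189, 196 and 200, in NFIA-Tg 181, 199 and 198, for genotype by differentiation 162, 196 and 200, and for the contrast of iWAT with day 7 26, 169 and 198. Up to 17 unchanged genes were called as well. In the data 11.4% (iWAT) to 87.2% (differentiation in NFIA-Tg) of genes were called, far more than were seeded, so recovery of small changes can differ there. Simulated genes were drawn independently, so the list tests were not tried with correlated members. Alternatives were a pseudocount of 0.1 or 0.5, no filter or a filter at FPKM 5, median-of-ratios, TPM or quantile scaling, no trend, robust eBayes, sample weights, and all 18 samples or only the compared groups in the fit. Further ones were the replicate number as a block, the highest entry per symbol in place of the sum, a minimum log2 change of 1, camera with an estimated correlation, fry, and each library left out in turn. Chosen after the data were seen were limma voom on the recovered culture reads, the fit without 3 culture libraries that stand apart, and 3 further gene lists. P-values of these 3 lists were adjusted over the 3 alone, which is less strict than the adjustment of the fixed lists. Figures were drawn with matplotlib 3.10.9 (python 3.11.15, numpy 2.4.6).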

Results

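RNA-seq was carried out on polyadenylated RNA from mouse inguinal white adipose tissue (iWAT), the subcutaneous fat depot of the groin, and from adipocyte cultures grown from the stromal-vascular cells of that depot. Genotypes were wild type (WT) and NFIA-Tg, mice or cells with a transgene for NFIA, a transcription factor of the nuclear factor I family encoded by Nfia. The promoter that drives the transgene is not given in the sources used here. Cultures were sampled before (day 0) and after (day 7) adipogenic induction with a cocktail of isobutylmethylxanthine, indomethacin, dexamethasone, insulin, T3 and rosiglitazone. The 6 groups held 3 samples each, 18 in all. By its title, the series asked how NFIA acts on mitochondrial and inflammatory genes of fat cells. The culture libraries held 16772594 to 28625625 recovered reads each. The read depth of the iWAT libraries is unknown, and their FPKM summed to 444682 to 487844. Within groups, log2(FPKM + 1) correlated across genes with r of 0.988 to 0.993 in iWAT and 0.997 to 0.998 in cultures, and no pair of libraries held identical values. Whether replicates came from separate animals or cultures is not stated, so p-values measure only the spread between these samples, which may be technical. Levels below are mean ± SD in FPKM (n = 3 per group), and log2 changes are on the log2(FPKM + 1) scale ± SE. In every gene called in iWAT, at day 0 or at day 7 that is named below, the 3 values of one genotype lay above the 3 of the other. The naming rule required this of the largest changes and took most others by small adjusted p, so it is no separate evidence.

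Nfia itself was measured first. In iWAT it stood at 3.73, 4.19 and 3.94 FPKM in the 3 WT libraries and at 166, 99.6 and 157 FPKM in the 3 NFIA-Tg libraries (log2 change 4.81 ± 0.18, adjusted p = 3.77e-05). At day 0 it was 6.42, 6.3 and 6.51 FPKM in WT and 11.3, 12.5 and 11.9 FPKM in the libraries labelled NFIA-Tg (log2 change 0.80 ± 0.05, adjusted p = 6.75e-08). At day 7 the order was the opposite, with 12.5, 13 and 12 FPKM in WT and 6.44, 7.32 and 7.2 FPKM in the libraries labelled NFIA-Tg (log2 change −0.76 ± 0.05, adjusted p = 3.34e-08). The Nfia level at day 7 therefore goes against its label, and the culture groups are called by their labels throughout. Directions given for the cultures are those of the labels. A genotype effect in the cultures means a difference between the labelled groups. Whether it comes from the transgene or from other differences between the cultures cannot be told apart here.

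**Figure D1:**
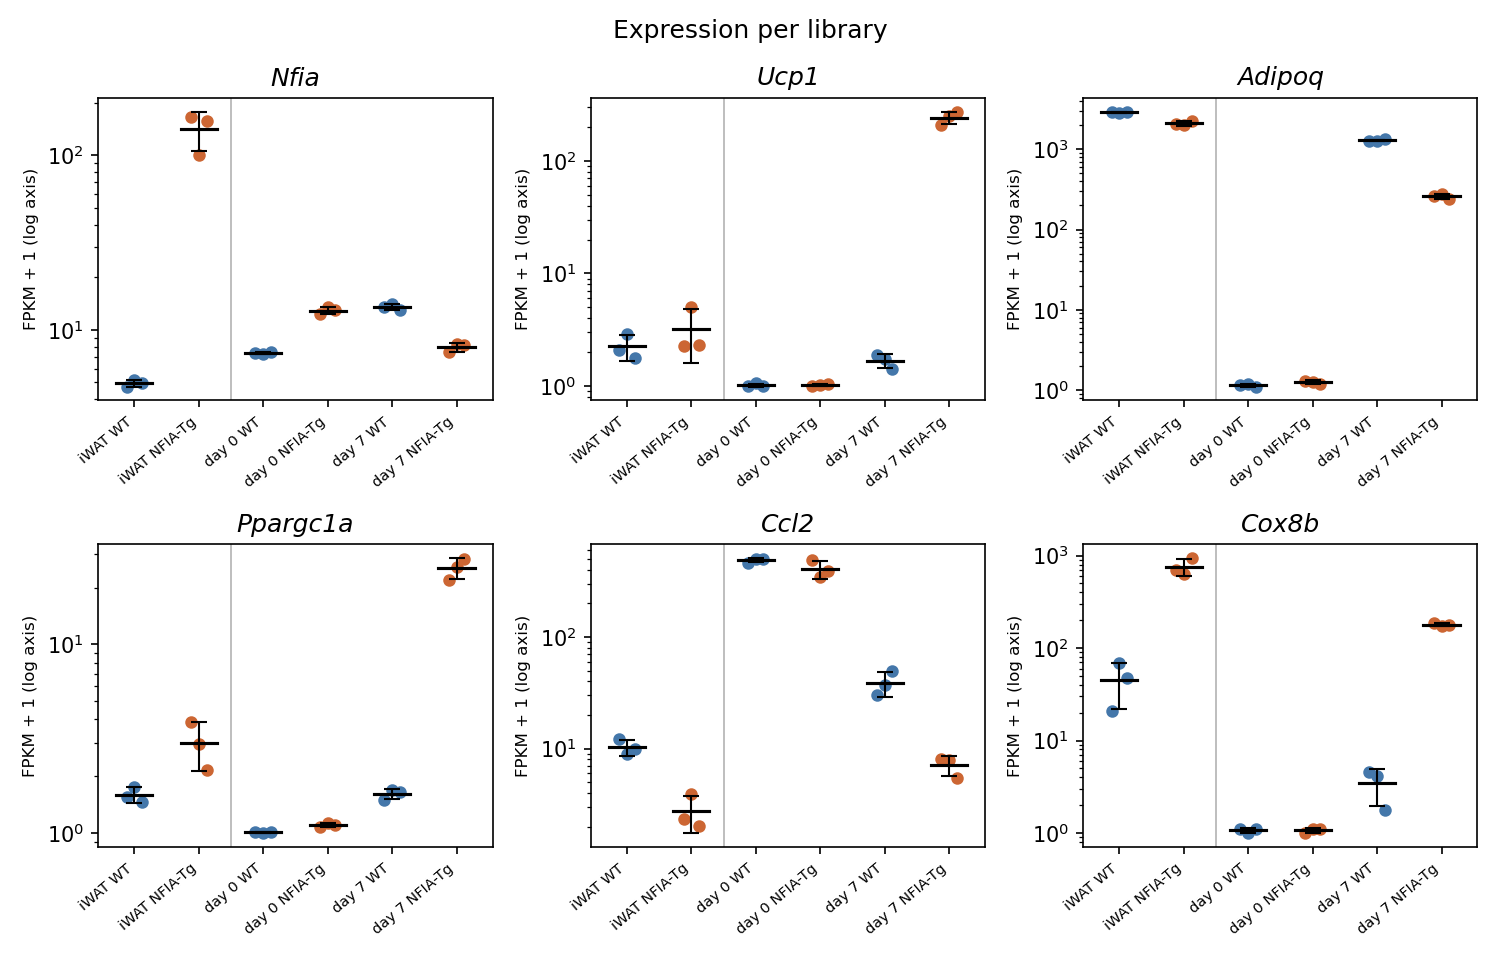
Expression of Nfia, Ucp1, Adipoq, Ppargc1a, Ccl2 and Cox8b in the 6 groups, as FPKM + 1 on a log axis; points are the 3 libraries, the bar is their mean and the error bar their SD, with WT in blue and NFIA-Tg in orange, and a grey line parts iWAT from the cultures. Mean Nfia is 141 FPKM in NFIA-Tg iWAT against 3.96 in WT, while at day 7 it is 6.99 FPKM in the libraries labelled NFIA-Tg against 12.5 in WT.

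In iWAT, genes of mitochondrial energy metabolism were higher in NFIA-Tg than in WT. Cox8b and Cox7a1, cytochrome c oxidase subunits of brown fat and muscle, both rose. Cox8b went from 44.4 ± 23.7 to 758 ± 162 FPKM (log2 change 4.20 ± 0.38, adjusted p = 0.000884). Cox7a1 went from 13.1 ± 1.1 to 43.7 ± 11 FPKM (log2 change 1.64 ± 0.17, adjusted p = 0.00147). Pdha1, a subunit of pyruvate dehydrogenase, rose from 83.3 ± 7.45 to 157 ± 12.3 FPKM (log2 change 0.91 ± 0.11, adjusted p = 0.00275). Suclg2, a subunit of succinyl-CoA synthetase, rose by 0.77 on the log2 scale. Echs1 and Eci1, enzymes of fatty acid β-oxidation, rose from 144 ± 15.3 to 256 ± 19.5 FPKM (log2 change 0.83) and from 117 ± 7.26 to 194 ± 2.81 FPKM (log2 change 0.73). Akt2, a kinase of insulin signalling, rose from 114 ± 14.9 to 192 ± 29.5 FPKM (log2 change 0.74). Adjusted p for Suclg2, Echs1, Eci1 and Akt2 was 0.00354 to 0.0167. Ucp1, the uncoupling protein of thermogenic fat, was low and did not pass the test, at 1.25 ± 0.564 FPKM in WT and 2.22 ± 1.61 in NFIA-Tg (adjusted p = 0.418). Pparg, the adipogenic nuclear receptor, was at 113 ± 24.6 and 122 ± 40.9 FPKM (adjusted p = 0.874). Nfib, Nfic and Nfix did not pass either (log2 changes 0.20, −0.20 and 0.18). The oxidative phosphorylation list had 31 of 79 measured members higher and 0 lower (46 and 1 adjusted over the list alone), with a median log2 change of 0.36. The tricarboxylic acid cycle list had 13 higher and 0 lower of 19 (15 and 1 over the list alone) and fatty acid oxidation 10 higher and 0 lower of 20 (16 and 0 over the list alone). Thermogenic genes had 11 higher and 1 lower of 22 (12 and 1 over the list alone), and glucose uptake and insulin signalling 8 higher and 0 lower of 28 (13 and 2 over the list alone). By camera, adjusted p was 2.17e-13, 1.40e-07, 1.40e-07, 0.000526 and 0.0116 in that order. None of these 5 held with an estimated correlation (adjusted p = 0.370 with an estimated correlation for each). By fry, adjusted p of the 5 was 0.0113 to 0.0317. Neither the mature adipocyte list (2 higher and 1 lower of 27, 4 and 3 over the list alone, adjusted p = 0.358) nor lipid synthesis (2 higher and 2 lower of 24, 3 and 2 over the list alone, adjusted p = 0.664) was called. In lipid synthesis the median log2 change was 0.08 while the mean (−0.07) and the test pointed down.

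Called members of the matrix, endothelial, lymphocyte and proliferation lists were mostly lower in NFIA-Tg iWAT. Ccl2, a chemokine that attracts monocytes, fell from 9.3 ± 1.67 to 1.77 ± 1.02 FPKM (log2 change −1.94 ± 0.25, adjusted p = 0.00341). Hp, the acute-phase protein haptoglobin, fell from 3404 ± 491 to 1017 ± 199 FPKM (log2 change −1.75 ± 0.20, adjusted p = 0.00227). Postn and Col16a1, proteins of the extracellular matrix, fell from 91.9 ± 14.5 to 28.1 ± 2.38 FPKM (log2 change −1.67) and from 17.8 ± 3.43 to 4.55 ± 0.863 FPKM (log2 change −1.76). The desaturases Scd1 and Scd2 fell from 4735 ± 963 to 721 ± 222 FPKM (log2 change −2.75) and from 49.4 ± 10.9 to 13.6 ± 1.93 FPKM (log2 change −1.77). Adipoq, the adipokine adiponectin, was 2903 ± 37.6 FPKM in WT and 2115 ± 139 in NFIA-Tg without passing the test (adjusted p = 0.0760). It did pass with TPM, no trend, robust eBayes, sample weights or all 18 samples in 1 fit (4.04e-05 to 0.637 over all its alternatives). The largest increases beside Nfia and Cox8b were in Pon1, which encodes paraoxonase, and Angptl7 (log2 changes 5.59 and 4.19). The largest decreases were in the integrin Itgad, the oxytocin receptor Oxtr, the ubiquitin-like Ubd and Lctl (log2 changes −3.86, −3.67, −3.67 and −2.91). Called markers of other cell types were Robo4 of endothelium, Lyz1 of macrophages, Synpo2 of smooth muscle, Acta1 of skeletal muscle, Cldn15 of mesothelium and Cdk1 of dividing cells, which fell (log2 changes −0.77, −1.66, −1.33, −2.64, −0.99 and −0.99). S100b, a member of the Schwann cell and nerve list, rose (1.88). For the called genes after Hp, adjusted p was 0.000195 to 0.00959. The extracellular matrix and fibrosis list had 3 of 45 measured members higher and 9 lower (3 and 12 adjusted over the list alone, adjusted p = 0.000214). Endothelial markers had 0 higher and 7 lower of 16 (0 and 10 over the list alone), proliferation genes 0 higher and 5 lower of 26 (0 and 12 over the list alone), and B and T lymphocyte markers 0 higher and 2 lower of 10 (0 and 4 over the list alone). Their medians were −0.50, −0.48 and −0.67, with adjusted p of 2.04e-07, 2.04e-07 and 0.000715. The 4 lists did not hold with an estimated correlation (adjusted p = 0.370 with an estimated correlation for each). By fry, adjusted p was 0.0362 for matrix, 0.0314 for endothelial markers and 0.0314 for proliferation, while the lymphocyte call was lost (0.110). Of preadipocyte and fibroblast markers 0 of 20 were called by limma and 4 had an unadjusted p under 0.05 (adjusted p of the list 0.664; mean and median above 0, test pointing down). The interferon-stimulated list was not called (2 higher and 0 lower of 42, 0 and 0 over the list alone, adjusted p = 0.863; mean and median above 0, test pointing down). Not called either were the neutrophil and mast cell (1 higher and 0 lower of 8, 2 and 0 over the list alone, 0.399, but 0.0386 with a filter at FPKM 5) and Schwann cell and nerve lists (1 higher and 0 lower of 10, the same over the list alone, 0.449).

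Other calls in iWAT were lost when a single library was left out. Cidea, a lipid droplet protein of thermogenic fat, rose from 13.5 ± 11 to 54.8 ± 5.42 FPKM (log2 change 2.24 ± 0.48, adjusted p = 0.0232). Adjusted p was 0.0692 without WT replicate 3, 0.0723 without NFIA-Tg replicate 2 and 0.0658 without NFIA-Tg replicate 3 (0.000137 to 0.0741 over all its alternatives), and the call was also lost with no filter and with robust eBayes. Ppargc1a, a coactivator of mitochondrial biogenesis, rose from 0.590 ± 0.152 to 2.01 ± 0.867 FPKM (log2 change 0.88 ± 0.23, adjusted p = 0.0424). Adjusted p was 0.0886, 0.0714 and 0.124 without WT replicate 1, 2 or 3 and 0.0798 with no filter (0.000353 to 0.124 over all its alternatives). Of 41 named genes called in iWAT, 14 lost the call without at least 1 library. Beside Cidea and Ppargc1a these were Mrpl47 (0.80) and Mrps5 (0.47) of the mitochondrial ribosome, the lipid and glycolysis enzymes Gpd1 (0.84) and Ldha (0.76), and the fatty acid carrier Fabp5 (−0.83), with the log2 change of each in parentheses. The others were Tnfrsf1b (−0.72) and Tnfaip2 (−0.84) of NF-kB signalling, the interferon-inducible GTPases Irgm2 (0.52) and Igtp (0.63), Cd52 (−0.90) of lymphocytes, S100a8 (1.58) of neutrophils and the stress gene Gadd45b (0.82). With no filter, Gpd1, Fabp5, Tnfrsf1b, Tnfaip2, Irgm2, Igtp, S100a8 and Gadd45b were lost too (adjusted p 0.0577 to 0.0980). So was Gpd1 with median-of-ratios (0.0515) or quantile scaling (0.0687), Irgm2 and Igtp with TPM (0.0559 and 0.0531) and S100a8 with robust eBayes (0.0730). Without WT replicate 1, 7 of the 14 were lost (adjusted p 0.0575 to 0.0901). Without WT replicate 2 the number was 7 (0.0502 to 0.103). Without WT replicate 3 the number was 12 (0.0615 to 0.125). Without NFIA-Tg replicate 1 the number was 3 (0.0724 to 0.0860). Without NFIA-Tg replicate 2 the number was 10 (0.0517 to 0.108). Without NFIA-Tg replicate 3 the number was 8 (0.0552 to 0.0985).

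Some list calls in iWAT also changed when 1 library was left out. The mitochondrial ribosome list had 9 higher and 0 lower of 75 (the same over the list alone, adjusted p = 0.00726, and adjusted p = 0.747 with an estimated correlation). Without WT replicate 3 or NFIA-Tg replicate 3 adjusted p was 0.0677 and 0.0825 (range 4.39e-05 to 0.0825; for lists, ranges are over the alternatives at the preset correlation). The list of inflammatory cytokines and chemokines had 3 higher and 6 lower of 32 (5 and 9 over the list alone), a median of −0.18 and adjusted p = 0.0266 (adjusted p = 0.385 with an estimated correlation). This call was lost without WT replicate 3 (0.0849), NFIA-Tg replicate 1 (0.0799) or NFIA-Tg replicate 2 (0.0649), and with no filter, all 18 samples in 1 fit, quantile or median-of-ratios scaling (0.0529 with the last; range 0.00156 to 0.103). Macrophage markers had 1 higher and 5 lower of 31 (2 and 9 over the list alone, adjusted p = 0.0431, and adjusted p = 0.772 with an estimated correlation). The call was lost without WT replicate 3 (0.362), NFIA-Tg replicate 1 (0.134) or NFIA-Tg replicate 3 (0.0825), and with no filter, a filter at FPKM 5, sample weights, all 18 samples or median-of-ratios scaling (0.0529 with the last; range 0.00463 to 0.362). Pericyte and smooth muscle markers had 1 higher and 1 lower of 14 (the same over the list alone, adjusted p = 0.0499, and adjusted p = 0.385 with an estimated correlation). This call was also lost without WT replicate 1 (0.193), NFIA-Tg replicate 2 (0.156) or NFIA-Tg replicate 3 (0.0509), and with no filter, sample weights, all 18 samples, the highest entry per symbol, quantile or median-of-ratios scaling (0.0638 with the last; range 0.0155 to 0.193). Fry ended the calls of the mitochondrial ribosome (adjusted p = 0.205), inflammatory (0.203), macrophage (0.464) and pericyte and smooth muscle (0.203) lists. Lists not called with all 6 libraries were NF-kB (0 higher and 3 lower of 32, the same over the list alone, adjusted p = 0.0803), skeletal muscle (1 higher and 1 lower of 8, 1 and 2 over the list alone, 0.194) and immediate-early and stress (2 higher and 2 lower of 24, 2 and 3 over the list alone, 0.199). The same held for erythroid (0 of 8 called by limma and 0 at an unadjusted p under 0.05, adjusted p of the list 0.149) and cytosolic ribosome (0 of 76 called and 1 at an unadjusted p under 0.05, 0.181). NF-kB passed without WT replicate 2 (0.0412) or NFIA-Tg replicate 1 (0.0387), skeletal muscle without WT replicate 2 (0.0247), and erythroid without WT replicate 2 (0.0269), WT replicate 3 (0.0155) or NFIA-Tg replicate 3 (0.0191). Immediate-early and stress passed without WT replicate 2 (0.0265) or NFIA-Tg replicate 1 (0.00434), and cytosolic ribosome without WT replicate 2 (0.00338), WT replicate 3 (0.0140) or NFIA-Tg replicate 3 (0.00851). Over the alternatives at the preset correlation, adjusted p of these 5 lists was 0.0387 to 0.156, 0.0247 to 0.868, 0.0155 to 0.882, 0.00434 to 0.785 and 0.00338 to 0.697, in the order NF-kB, skeletal muscle, erythroid, immediate-early and cytosolic ribosome. Mammary epithelial and mesothelial lists had under 5 measured genes in each comparison and were not tested.

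Of 12396 genes tested in iWAT, 1413 were called, 739 higher and 674 lower in NFIA-Tg, and 3543 had an unadjusted p under 0.05. With median-of-ratios scaling the split was 602 higher and 810.0 lower, and with quantile normalization 665 and 819. The count was 617 without WT replicate 3, 638 without NFIA-Tg replicate 2, 745 without NFIA-Tg replicate 3 and 814 without WT replicate 2. It was also 934 with no filter on low values, 2524 with sample weights and 5141 when all 18 samples shared 1 estimate of the spread.

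At day 0, before induction, cultures labelled NFIA-Tg had more transcript of adipocyte genes and less of proliferation and interferon-stimulated genes than WT cultures. Pparg rose from 3.69 ± 0.0194 to 15.2 ± 1.23 FPKM (log2 change 1.79 ± 0.05, adjusted p = 6.05e-11). Plin4, a lipid droplet coat protein, rose from 0.593 ± 0.0846 to 10.2 ± 0.400 FPKM (log2 change 2.81 ± 0.07, adjusted p = 2.79e-11). Top2a, a topoisomerase of dividing cells, fell from 53.8 ± 0.747 to 18.1 ± 0.709 FPKM (log2 change −1.52 ± 0.04, adjusted p = 2.82e-11). The antiviral synthetases Oas3 and Oas1a fell from 10.2 ± 2.58 to 1.16 ± 0.840 FPKM (log2 change −2.42) and from 41.7 ± 7.5 to 11.3 ± 3.94 FPKM (log2 change −1.83). Saa3, an acute-phase serum amyloid, fell from 676 ± 279.7 to 31 ± 13.5 FPKM (log2 change −4.41). Ccl2, at 486 ± 21.7 and 406 ± 74.2 FPKM, did not pass (adjusted p = 0.219). Zfp423, a transcription factor of committed preadipocytes, rose from 0.322 ± 0.0837 to 4.81 ± 0.168 FPKM (log2 change 2.14), and Ebf2, a factor of brown preadipocytes, from 1.81 ± 0.167 to 5.05 ± 0.127 FPKM (log2 change 1.11). Ucp1, Cidea, Ppargc1a and Adipoq had mean levels under 1 FPKM in both groups and did not pass (adjusted p = 0.974, 0.536, 0.184 and 0.0841). Ppargc1a and Adipoq did pass with a pseudocount of 0.5 (0.0422 and 0.0311; ranges 0.000208 to 0.549 and 0.0150 to 0.959), and likewise with a pseudocount of 0.1 or with TPM. Ppargc1a also passed with voom. Adipoq also passed without day 0 NFIA-Tg replicate 3 (0.0292) and without 3 culture libraries that stand apart (0.0437).

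Among the other genes at day 0, the largest increases were in Gdf10, Apoe, Kctd12 and Cox6b2 (log2 changes 3.60, 3.48, 3.47 and 3.42). The largest decreases after Saa3 were in Xlr, Aldh1a2 and Xlr3b (−3.19, −3.10 and −3.01). Xlr3b was listed at 0 in the 3 libraries labelled NFIA-Tg, and Xlr and Xlr3b belong to a multicopy family whose reads can be shared. Higher genes also included Cox6c (1.36) and Ndufb9 (0.73) of the respiratory chain, Etfb (0.52) and Acadm (0.64) of fatty acid oxidation, Mrps6 (0.80) and Mrpl13 (0.39) of the mitochondrial ribosome, and the acyltransferase Dgat1 (0.80), with the log2 change in parentheses. Further genes that rose were Ldhb (1.42), the hormone Fgf21 (0.71), the adhesion molecule Icam1 (3.06), the prostaglandin synthase Ptges (1.48), Irak3 (0.58) and Il1r1 (0.79) of interleukin-1 signalling, and the matrix genes Eln (1.72) and Col15a1 (1.84). Lower genes included Pdha1 (−0.49), Elovl5 (−0.69), Tpi1 (−1.14), Nfic (−0.21), Rps4x (−0.58), Nr4a2 (−0.79), Kdr (−1.10) and Ngfr (−1.22), and markers of other cell types that were higher were Cd14 (0.70), Camp (1.37), Notch3 (1.10), Actn3 (1.33) and Cldn15 (3.23). Nfib rose from 0.379 ± 0.0342 to 1.51 ± 0.145 FPKM (log2 change 0.86). Nfix, with a log2 change of 0.10, did not pass (adjusted p = 0.0509). It did with no filter, quantile normalization, sample weights or median-of-ratios scaling (0.00696 with the last), and without day 0 NFIA-Tg replicate 1 (0.0216) or day 7 NFIA-Tg replicate 2 (0.0480; range 0.00696 to 0.693). Prlr, a member of the mammary epithelial list, had a log2 change of 0.18 (adjusted p = 0.0423). This call was lost without any 1 of the 6 day 0 libraries or day 7 WT replicate 2 (0.0522 to 0.110), with no filter (0.0577) and with all 18 samples in 1 fit (0.0670). The call of Nfic was also lost with all 18 samples (0.147). Mature adipocyte genes had 14 of 24 measured members higher and 2 lower (14 and 2 adjusted over the list alone), a median of 0.39 and adjusted p = 0.000185. Lipid synthesis had 12 higher and 1 lower of 24 (the same over the list alone, adjusted p = 0.0128). Preadipocyte and fibroblast markers had 12 higher and 3 lower of 20 (the same over the list alone, adjusted p = 0.00205). The interferon-stimulated list had 1 higher and 37 lower of 42 (1 and 38 over the list alone), median −0.91, adjusted p = 3.62e-05. Proliferation had 0 higher and 34 lower of 35 (the same over the list alone), median −1.22, adjusted p = 2.20e-18. None of the 5 held with an estimated correlation (adjusted p = 0.580, 0.984, 0.686, 0.986 and 0.137 with an estimated correlation, in that order). By fry, adjusted p of the 5 was 8.67e-10 to 0.0124. Lipid synthesis was also lost when all 18 samples shared a fit (0.0958; range 0.00327 to 0.0958). Oxidative phosphorylation had 30 higher and 15 lower of 78 (29 and 13 over the list alone) and was not called (adjusted p = 0.125). It passed without day 0 NFIA-Tg replicate 2 (0.0443) and when the fit held day 0 samples only (0.0333; range 0.0333 to 0.198). Inflammatory cytokines and chemokines went both ways (12 higher and 13 lower of 31, the same over the list alone, adjusted p = 0.875), with mean and median below 0 and the test pointing up. Of 12553 genes, 7911 were called at day 0, 3533 higher and 4378 lower, of which 777 changed by at least 1 on the log2 scale. With median-of-ratios scaling 3947 and 3878 were higher and lower.

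At day 7, thermogenic genes were far higher in the cultures labelled NFIA-Tg than in WT cultures. Ucp1 rose from 0.675 ± 0.235 to 241 ± 30.4 FPKM (log2 change 7.18 ± 0.10, adjusted p = 8.28e-14). Cidea rose from 0.169 ± 0.122 to 23.5 ± 0.318 FPKM (log2 change 4.39 ± 0.07, adjusted p = 2.82e-13) and Ppargc1a from 0.614 ± 0.0992 to 24.4 ± 3.25 FPKM (log2 change 3.97 ± 0.08, adjusted p = 1.26e-12). Cox8b and Cox7a1 rose from 2.45 ± 1.49 to 178 ± 7.42 FPKM (log2 change 5.81) and from 9.63 ± 5.13 to 429.5 ± 2.86 FPKM (log2 change 5.46). Other respiratory chain genes that rose were Cox6a2 (2.94) and Ndufb9 (1.52), with Sucla2 (1.25) of the tricarboxylic acid cycle, the acyl-CoA thioesterase Acot2 (1.97), and Mrpl13 (1.12) and Mrpl24 (0.89) of the mitochondrial ribosome, log2 changes in parentheses. Cpt1a, which brings fatty acids into mitochondria, fell from 25.6 ± 1.79 to 6.07 ± 0.244 FPKM (log2 change −1.91). Adipoq fell from 1295 ± 26.8 to 258 ± 17.9 FPKM (log2 change −2.32 ± 0.06, adjusted p = 3.99e-12). Fasn and Acaca, enzymes of fatty acid synthesis, fell from 697 ± 41.2 to 91.5 ± 3.97 FPKM (log2 change −2.92) and from 127 ± 5.53 to 31.6 ± 2.55 FPKM (log2 change −1.97). The adrenergic receptor Adrb3 fell from 9.28 ± 0.791 to 0.743 ± 0.0477 FPKM (log2 change −2.56). Pparg was at 70.7 ± 1.56 and 72.5 ± 1.19 FPKM and did not pass (adjusted p = 0.504). It did with median-of-ratios scaling (log2 change 0.17, adjusted p = 0.00488; range 0.00488 to 0.906). Thermogenic genes had 18 of 23 measured members higher and 4 lower (18 and 4 adjusted over the list alone, median 0.99, adjusted p = 7.47e-07). Oxidative phosphorylation had 59 higher and 4 lower of 78 (the same over the list alone, median 0.42, adjusted p = 9.44e-12). The tricarboxylic acid cycle had 14 higher and 3 lower of 19 (the same over the list alone) and the mitochondrial ribosome 39 higher and 14 lower of 75 (the same over the list alone, adjusted p = 0.000288 and 0.000240). Glucose uptake and insulin signalling had 21 higher and 4 lower of 27 (the same over the list alone, adjusted p = 0.000137). Among them Trib3, an inhibitor of AKT, rose from 27.6 ± 1.37 to 238 ± 11 FPKM (log2 change 3.07), and the phosphofructokinase Pfkp rose as well (2.87). These 5 lists did not hold with an estimated correlation (adjusted p = 0.322, 0.434, 0.322, 0.500 and 0.434 with an estimated correlation, in that order). By fry, adjusted p of the 5 was 2.36e-09 to 0.000161. Fatty acid oxidation (10 higher and 6 lower of 20, the same over the list alone, adjusted p = 0.0633) was not called. It passed without day 7 WT replicate 1 (0.0431) and with median-of-ratios scaling (0.0420; range 0.0420 to 0.410). Mature adipocyte genes (5 higher and 12 lower of 24, the same over the list alone, 0.384) and lipid synthesis (8 higher and 14 lower of 24, the same over the list alone, 0.673) were not called either. The former passed with quantile normalization (0.0126, range 0.0126 to 0.602). By fry, fatty acid oxidation passed upward (adjusted p = 0.000488), and mature adipocyte genes (2.69e-07) and lipid synthesis (4.35e-06) passed downward. Fry does not set a list against the other genes, and 80.9% of the genes tested were called at day 7.

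Matrix, stromal, inflammatory, interferon and proliferation genes were lower at day 7 in the cultures labelled NFIA-Tg. Col1a2 and Col3a1, fibrillar collagens, both fell. Col1a2 went from 458 ± 24.8 to 56.4 ± 7.91 FPKM (log2 change −3.01 ± 0.08, adjusted p = 9.24e-12) and Col3a1 from 533 ± 28.3 to 66.3 ± 8.5 FPKM (log2 change −3.00). Thy1, a surface protein of stromal cells, fell from 66.1 ± 6.93 to 11.7 ± 0.510 FPKM (log2 change −2.40). Ccl2 fell from 38 ± 9.95 to 6.14 ± 1.48 FPKM (log2 change −2.44 ± 0.19, adjusted p = 8.11e-08). The chemokine Cxcl12 and adhesion molecule Vcam1 fell from 63.3 ± 5.13 to 5.81 ± 0.278 FPKM (log2 change −3.24) and from 24.1 ± 2.3 to 3.97 ± 0.405 FPKM (log2 change −2.34). Oas2 and Oas1a had log2 changes of −2.83 and −2.71. For the interleukin-1 receptor Il1r1 and the NF-kB inhibitor Tnfaip3 they were −1.89 and −1.60, and for Rrm2, a subunit of ribonucleotide reductase, −1.81. The largest decreases were in the iron carrier Trf (from 201 ± 5.07 to 2.65 ± 0.500 FPKM), Saa3, Dcn and Ngfr (log2 changes −5.80, −4.56, −4.39 and −4.05). Among the 4 largest increases was the phospholipase Pla2g2e (5.16). Ddit3, a stress-induced transcription factor, rose from 58.5 ± 2.91 to 844 ± 38.2 FPKM (log2 change 3.83). Among nuclear factor I genes, Nfib rose (0.99) while Nfic and Nfix fell (log2 changes −1.25 and −1.65). Members of the marker lists went both ways, Cd68 (1.13), Pecam1 (1.81), Prlr (2.17) and Mb (2.32) higher and Elane (−0.98), Mcam (−1.86) and Cldn15 (−0.76) lower. Whether they report other cell types in these cultures was not tested. Rps4x, of the cytosolic ribosome, fell (−1.01). Pecam1, of endothelium, reached 2.98 ± 0.320 FPKM. Matrix and fibrosis had 1 of 47 measured members higher and 44 lower (1 and 44 adjusted over the list alone, median −1.58, adjusted p = 3.13e-09). Preadipocyte and fibroblast markers had 1 higher and 16 lower of 20 (the same over the list alone, median −1.27, adjusted p = 0.00285). Proliferation had 0 higher and 34 lower of 35 (the same over the list alone, median −1.29, adjusted p = 8.38e-09). Inflammatory cytokines and chemokines had 4 higher and 23 lower of 31 (the same over the list alone, median −1.20, adjusted p = 0.0238). With an estimated correlation these 4 were lost (adjusted p = 0.434, 0.434, 0.322 and 0.597 with an estimated correlation). By fry, adjusted p of the 4 was 8.26e-10 to 1.17e-06. Interferon-stimulated genes had 0 higher and 34 lower of 42 (the same over the list alone, median −1.10, adjusted p = 0.0207, and adjusted p = 0.746 with an estimated correlation). This call was lost without day 7 NFIA-Tg replicate 1 (0.0672) or NFIA-Tg replicate 3 (0.0531), with sample weights (0.0604) and without 3 culture libraries that stand apart (0.0531; range 3.46e-05 to 0.0672). By camera, the NF-kB list was not called (10 higher and 18 lower of 32, 10 and 19 over the list alone, adjusted p = 0.582). Neither were the macrophage, pericyte and smooth muscle, skeletal muscle, Schwann cell and nerve, immediate-early and stress, and cytosolic ribosome lists (adjusted p = 0.610, 0.219, 0.442, 0.301, 0.583 and 0.785). Median and camera differed in sign for macrophage, skeletal muscle and cytosolic ribosome. By fry, the NF-kB, macrophage, pericyte, skeletal muscle and Schwann cell lists passed (adjusted p = 1.73e-07 to 0.00720). The immediate-early and cytosolic ribosome lists did not pass by fry. At day 7, 10155 of 12553 genes were called, 3746 higher and 6409 lower, of which 2184 changed by at least 1 on the log2 scale. Median-of-ratios scaling moved the median of all genes from −0.172 to −0.0597 (log2; difference 0.112), giving 4568 higher and 5422 lower. Quantile normalization moved it by 0.148 and gave 4718 and 5083.

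**Figure D2:**
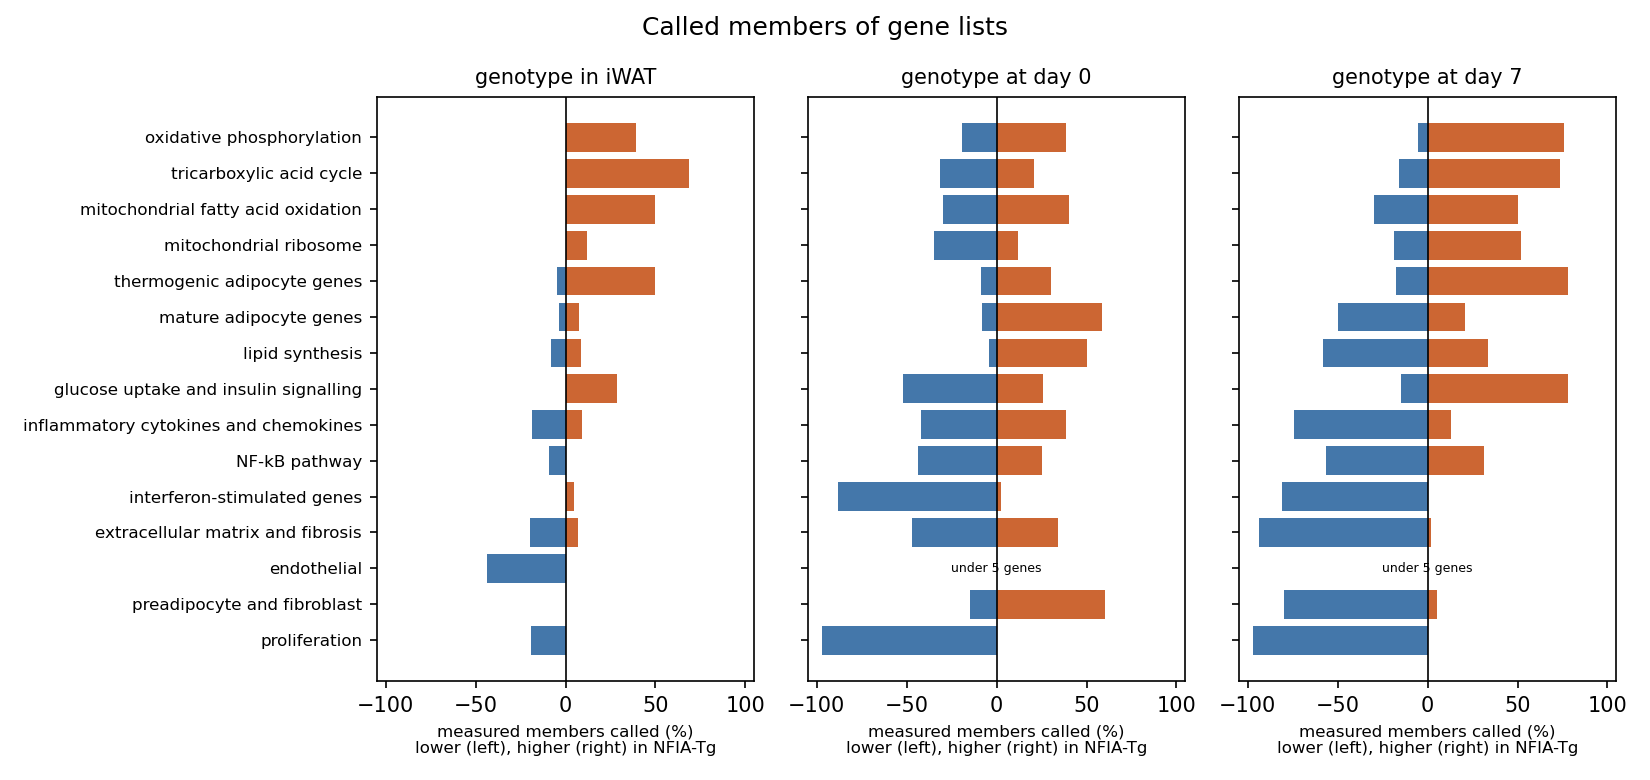
Percentage of the measured members of 15 gene lists called lower (bars to the left) or higher (bars to the right) in NFIA-Tg than in WT, in iWAT, at day 0 and at day 7; endothelial markers had under 5 measured genes in the cultures. Oxidative phosphorylation members called higher number 31 of 79 in iWAT and 59 of 78 at day 7, and matrix members called lower 9 of 45 and 44 of 47.

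Differentiation of WT cultures from day 0 to day 7 raised adipocyte, lipid and mitochondrial genes. Adipoq rose from 0.150 ± 0.0460 to 1295 ± 26.8 FPKM (log2 change 10.14 ± 0.06, adjusted p = 5.11e-18). The fatty acid carrier Fabp4 rose from 7.76 ± 1.11 to 22169 ± 2243 FPKM (log2 change 11.31 ± 0.15, adjusted p = 2.90e-15) and the fatty acid transporter Cd36 from 0.150 ± 0.0197 to 537 ± 8.74 FPKM (log2 change 8.87 ± 0.04, adjusted p = 2.59e-19). Cidec, a lipid droplet protein, and Cfd, the adipokine adipsin, had log2 changes of 10.16 and 9.52. Pparg rose from 3.69 ± 0.0194 to 70.7 ± 1.56 FPKM (log2 change 3.93), and the insulin-responsive glucose transporter Slc2a4 from 0.105 ± 0.0286 to 68.5 ± 6.15 FPKM (log2 change 5.97). Mitochondrial genes that rose were Uqcrc2 (2.51), Sdha (2.20), Pcx (5.80), Idh3a (3.82), Hadhb (3.35), Acsl1 (7.07), Mrpl12 (2.33) and Mrpl20 (1.38), and Ucp1 reached only 0.675 ± 0.235 FPKM. Elovl3 and Kcnk3 of the thermogenic list rose (6.72 and 4.45), as did Agpat2, Me1, Orm1, Ptges and Zfp423 (6.01, 4.16, 6.90, 1.83 and 2.64). The chemokine genes Ccl2 and Cxcl5 fell from 486 ± 21.7 to 38 ± 9.95 FPKM (log2 change −3.67) and from 114 ± 29.3 to 2.13 ± 0.583 FPKM (log2 change −5.18). So did the matrix genes and receptors Itga11 (−4.58), Cpxm1 (−4.42), Fndc1 (−4.09), Fmod (−2.93) and Col5a2 (−2.54) and the NF-kB inhibitors Nfkbie (−1.48) and Nfkbiz (−1.64). Nfia and Nfib rose (0.87 and 2.58), Nfix fell (−1.23) and Nfic did not pass (adjusted p = 0.588), although it was lower under median-of-ratios, TPM and quantile scaling (4.81e-05 to 0.927 over its alternatives). Cidea did not pass either (adjusted p = 0.0750), but did without day 0 WT replicate 2 (0.0416) or day 7 WT replicate 3 (0.0260; range 0.0260 to 0.747) and with a pseudocount of 0.1, sample weights or voom. Other named genes that rose were Ppargc1a (0.68), Gbp6 (1.52), Gbp3 (1.46), Elane (1.17), Mcam (3.26), Prlr (1.44), Mbp (0.87), Cldn15 (1.88) and Rrm2 (2.13). Those that fell were Gpnmb (−2.29), Tek (−1.82), Junb (−2.46), Rpl5 (−0.86) and Tnnt3 (−1.45), where adjusted p was at most 1.06e-05 and the call of Tnnt3, a muscle marker, was lost with all 18 samples in 1 fit (0.0842). Mature adipocyte genes had 23 of 24 measured members higher and 1 lower (23 and 1 adjusted over the list alone) with a median of 6.72 (adjusted p = 1.13e-11). The tricarboxylic acid cycle had 19 higher and 0 lower of 19 (the same over the list alone), fatty acid oxidation 20 higher and 0 lower of 20 (the same over the list alone) and glucose uptake 20 higher and 7 lower of 27 (the same over the list alone, adjusted p = 1.49e-09, 2.88e-09 and 0.0426). Mature adipocyte, tricarboxylic acid cycle and fatty acid oxidation calls held with an estimated correlation (adjusted p = 0.0401 with an estimated correlation for each), and that of glucose uptake did not (adjusted p = 0.545 with an estimated correlation). Oxidative phosphorylation had 78 higher and 0 lower of 78 (the same over the list alone), the mitochondrial ribosome 72 higher and 1 lower of 75 (the same over the list alone) and thermogenic genes 18 higher and 3 lower of 23 (the same over the list alone). Lipid synthesis had 22 higher and 1 lower of 24 (the same over the list alone) and proliferation 34 higher and 1 lower of 35 (the same over the list alone). Lists that fell were inflammatory (4 higher and 23 lower of 31, the same over the list alone), NF-kB (8 higher and 19 lower of 32, the same over the list alone) and matrix and fibrosis (5 higher and 39 lower of 47, the same over the list alone). Others that fell were preadipocyte and fibroblast (5 higher and 14 lower of 20, the same over the list alone), immediate-early (2 higher and 20 lower of 26, the same over the list alone) and cytosolic ribosome (0 higher and 69 lower of 74, the same over the list alone). For these lists adjusted p was 4.46e-18 to 0.00483, and none held with an estimated correlation (adjusted p = 0.138 to 0.243 with an estimated correlation). In all, 10246 of 12553 genes were called, 5796 higher and 4450 lower at day 7. TPM and quantile scaling moved the median of all genes by −0.156 and −0.148 (log2) and gave 4632 and 5492 with TPM and 4738 and 5532 with quantile scaling.

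In cultures labelled NFIA-Tg, differentiation raised adipocyte genes and also thermogenic ones. Fabp4 rose from 16.6 ± 3.82 to 25679 ± 1814 FPKM (log2 change 10.53 ± 0.15, adjusted p = 4.31e-15). Cd36 rose from 0.118 ± 0.0179 to 782 ± 28.9 FPKM (log2 change 9.45 ± 0.04, adjusted p = 1.22e-19) and Adipoq from 0.250 ± 0.0727 to 258 ± 17.9 FPKM (log2 change 7.70 ± 0.06, adjusted p = 6.72e-17). Ucp1 rose from 0.0217 ± 0.0213 to 241 ± 30.4 FPKM (log2 change 7.88 ± 0.10, adjusted p = 2.93e-15). Cidea rose from 0.0106 ± 0.0183 to 23.5 ± 0.318 FPKM (log2 change 4.60), Ppargc1a from 0.103 ± 0.0217 to 24.4 ± 3.25 FPKM (log2 change 4.52) and Fgf21 from 1.6 ± 0.154 to 146 ± 6.18 FPKM (log2 change 5.82). Cidec, Thrsp, Gpd1, Elovl3 and Slc2a4 had log2 changes of 9.29, 8.84, 8.83, 7.69 and 6.13. The mitochondrial genes Uqcrc2 (3.36), Ndufa10 (2.54), Idh3a (4.67), Pdhb (4.31), Hadhb (3.97), Etfa (3.07), Mrpl12 (2.47) and Mrpl44 (2.08) rose by the log2 changes in parentheses. Matrix genes fell, among them Col3a1 from 4621 ± 178 to 66.3 ± 8.5 FPKM (log2 change −6.11) and Fn1 from 2225 ± 150.5 to 73.3 ± 4.3 FPKM (log2 change −4.90). Fbln1, Cpxm1 and the growth factor Ptn also fell (−6.56, −6.47 and −7.40). Ccl2, Cxcl5, Vcam1, Cxcl12 and Il1r1 fell too (−5.84, −6.60, −5.39, −4.66 and −3.92), and Thy1 fell from 409 ± 3.2 to 11.7 ± 0.510 FPKM (log2 change −5.01). Nfia, Nfic and Nfix fell (−0.69, −1.06 and −2.98) and Nfib rose (2.71). Other named genes that rose were Pparg (2.18), Agpat2 (4.77), Psmb9 (1.44), Oasl1 (2.47), Prlr (3.42), Mb (2.79), Mcm2 (1.71) and Ddit3 (3.30) in these cultures. Those that fell were Tnfrsf1a (−1.71), Cd14 (−2.18), Camp (−2.76), Tek (−2.78), Notch3 (−2.69), Pmp22 (−1.31), Cldn15 (−2.11) and Rps4x (−1.45) (adjusted p at most 1.50e-06). Mature adipocyte genes had 22 of 24 measured members higher and 1 lower (22 and 1 adjusted over the list alone) with a median of 5.77 (adjusted p = 1.19e-08). Thermogenic genes had 21 higher and 1 lower of 23 (the same over the list alone) with a median of 4.08 (adjusted p = 9.60e-07). Matrix and fibrosis had 1 higher and 46 lower of 47 (the same over the list alone) with a median of −3.45 (adjusted p = 5.72e-14). Oxidative phosphorylation had 78 higher and 0 lower of 78 (the same over the list alone) and preadipocyte and fibroblast markers 0 higher and 20 lower of 20 (the same over the list alone, adjusted p = 1.01e-17 and 2.24e-07). The tricarboxylic acid cycle, fatty acid oxidation, mitochondrial ribosome, lipid synthesis, glucose uptake and proliferation lists were also called higher (adjusted p = 6.21e-13 to 0.000151). The inflammatory, NF-kB, immediate-early and cytosolic ribosome lists were called lower (adjusted p = 1.19e-08 to 0.00412). None of these lists held with an estimated correlation (adjusted p = 0.0933 to 0.347 with an estimated correlation). In all, 10950 of 12553 genes were called, 5741 higher and 5209 lower at day 7. With TPM, which moved the median of all genes by −0.231 (log2), 4646 and 6308 were higher and lower. Of the genes tested, 4499 were called higher and 3647 lower in both genotypes, against 2651 and 1847 for independent lists (Fisher's exact test, two-sided, odds ratio 15.4, 95% CI 14.1 to 16.8, and 19, 17.3 to 20.9). The log2 changes correlated across genes with r = 0.790 and rho = 0.773, where genes are not independent replicates.

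The genotype by differentiation contrast tested whether the genotype effect at day 7 differed from that at day 0. It was positive for Ucp1 (log2 difference 7.17 ± 0.15, adjusted p = 4.75e-12), Cidea (4.45), Ppargc1a (3.84), the metallothionein Mt2 (5.97), Cox8b (5.82), Cox7a1 (5.35), Cox6a2 (3.56), Acot2 (2.25), Trib3 (3.10) and Psmb8 (1.15). It was negative for Adipoq (−2.44 ± 0.08, adjusted p = 1.10e-10), Pparg (−1.75), Fasn (−3.06), the lipase Mgll (−2.06), Ccl2 (−2.17), Ptges (−3.00), Il1r1 (−2.68), Eln (−3.13), Dcn (−4.48), Sned1 (−4.99), Adh1 (−5.23), Clec3b (−6.11), Pcx (−1.32) and Mrps6 (−1.29). It was also negative for Nfia (−1.56), Nfic (−1.04) and Nfix (−1.75). Nfib did not pass (0.12, adjusted p = 0.423), but did without day 7 NFIA-Tg replicate 1 (0.0246; range 0.00292 to 0.815) and with quantile normalization. It was negative and passed with a pseudocount of 0.1 (−0.68) or voom (−0.91). Ppargc1a, under 1 FPKM at day 0, did not pass with voom on recovered reads (0.135; range 4.43e-12 to 0.135). The mature adipocyte list had 3 higher and 20 lower of 24 (the same over the list alone), with a median difference of −1.14. Thermogenic genes had 17 higher and 5 lower of 23 (the same over the list alone, median 0.97) and oxidative phosphorylation 50 higher and 4 lower of 78 (the same over the list alone, median 0.36). The tricarboxylic acid cycle had 15 higher and 3 lower of 19 (the same over the list alone, median 0.49), the mitochondrial ribosome 40 higher and 7 lower of 75 (39 and 7 over the list alone, median 0.22) and glucose uptake 17 higher and 7 lower of 27 (the same over the list alone, median 0.72). Matrix and fibrosis had 1 higher and 42 lower of 47 (the same over the list alone, median −1.60) and preadipocyte and fibroblast markers 1 higher and 18 lower of 20 (the same over the list alone, median −2.38). For these 8 lists adjusted p was 0.000805, 3.76e-05, 7.65e-08, 0.000133, 0.000111, 0.00235, 2.50e-09 and 6.24e-06 in the order given. None held with an estimated correlation (adjusted p = 0.329 to 0.537 with an estimated correlation). The inflammatory list was not called (6 higher and 19 lower of 31, 6 and 20 over the list alone, adjusted p = 0.0566). Neither was the interferon-stimulated list (5 higher and 5 lower of 42, the same over the list alone, 0.671), whose mean and median lay below 0 with the test pointing up. Of 12553 genes, 9051 were called, 3701 positive and 5350 negative. Quantile normalization moved the median of all genes by 0.135 (log2) and gave 4713 and 4306, and median-of-ratios scaling gave 4285 and 4677.

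The genotype effect in iWAT was then compared with that at day 7. These tables were made differently, so only effects within each setting are compared, and directions at day 7 follow the labels. Genes called in both settings and in the same direction were more frequent than for independent lists. Over 10984 genes tested in both, 324 were higher in both, 205 for independent lists (Fisher's exact test, two-sided, odds ratio 2.26, 95% CI 1.92 to 2.66, p = 2.03e-23). A further 310 were lower in both, 252 for independent lists (odds ratio 1.66, 1.37 to 2.01, exact p = 6.84e-08). In the opposite sense, 252 genes higher in iWAT were lower at day 7, and 134 lower in iWAT were higher. Across genes the log2 changes correlated weakly (r = 0.165, rho = 0.176), and genes are not independent replicates. Called higher in both were 26 of 77 oxidative phosphorylation genes, 10 of 19 in the tricarboxylic acid cycle and 9 of 20 thermogenic genes. Called lower in both were 8 of 44 matrix genes, 5 of 26 inflammatory genes and 5 of 26 proliferation genes. Called in opposite directions were 1, 1, 3, 3, 3 and 0 genes of these lists, in that order. Of fatty acid oxidation 4 of 20 were higher in both and 3 opposite, of lipid synthesis 1 of 24 and 3, and of mature adipocyte genes 0 of 24 and 2. By the contrast of the 2 effects, that in iWAT exceeded that at day 7 for Nfia (5.56 ± 0.21, adjusted p = 8.62e-09), Pon1 (5.64, under 1 FPKM and not tested at day 7), Adipoq (1.86), Sfrp1 (4.99), Trf (4.75), Dcn (4.71), Acsl1 (3.19), Cpt1a (2.30), Acly (2.38), Cxcl12 (3.18), Csf1 (2.39), Oas2 (3.08), Nfic (1.05) and Nfix (1.83). It was below it for Ucp1 (−6.74 ± 0.39, adjusted p = 1.04e-07), Ppargc1a (−3.09), Cidea (−2.16), Scd1 (−4.42), Itgad (−5.57), Lctl (−5.21), Cela1 (−5.60), Cox6a2 (−4.11), Ndufa6 (−1.30), Trib3 (−2.90), Pfkp (−2.39), Ddit3 (−3.44), Pecam1 (−2.36), Acta1 (−3.22) and Nfib (−0.79). Ccl2 (0.50, adjusted p = 0.259) and Pparg (0.04, 0.918) did not pass. Krt19, a mesothelial marker, passed (adjusted p = 0.0381) but not without day 7 WT replicate 2, WT replicate 3 or NFIA-Tg replicate 2, or iWAT WT replicate 1, WT replicate 3, NFIA-Tg replicate 2 or NFIA-Tg replicate 3 (0.0652 to 0.0888), nor with no filter (0.0652; range over alternatives 0.00939 to 0.0888). Other named genes with the effect in iWAT above that at day 7 were Mpeg1 (adjusted p = 9.82e-06), Pdha1 (0.90), Mrpl49 (1.05), Car3 (2.75), Il1r1 (2.35), Cxcl9 (1.95), Col6a2 (2.08) and Rps4x (1.08), and Mrps10 (−0.73), Ikbkg (−1.23) and Des (−2.62) lay below (adjusted p at most 7.89e-05). Camp, Ngfr, Bub1 and Prlr, not tested in iWAT, differed by 0.89, 3.59, 1.81 and −2.06, and Cd52, not tested at day 7, by −0.90 (adjusted p at most 0.00234). Lists higher in the contrast were matrix (37 higher and 2 lower of 46, the same over the list alone), interferon-stimulated (34 higher and 0 lower of 43, 35 and 0 over the list alone), preadipocyte and fibroblast (15 higher and 0 lower of 21, the same over the list alone) and proliferation (24 higher and 0 lower of 35, 26 and 0 over the list alone). Lists lower were thermogenic (5 higher and 16 lower of 25, the same over the list alone), glucose uptake (5 higher and 12 lower of 28, the same over the list alone) and oxidative phosphorylation (12 higher and 19 lower of 78, 9 and 17 over the list alone). Of these 7 lists 44, 41, 19, 26, 20, 27 and 77 members were tested in both settings, and adjusted p was 2.22e-07, 1.83e-05, 0.000855, 0.000138, 0.000524, 0.0123 and 0.0350, each in the order given. None held with an estimated correlation (adjusted p = 0.375 to 0.883 with an estimated correlation). Camera sets a list against the other genes, and the median difference of all genes was 0.181. The oxidative phosphorylation list, with a median of −0.0451, was lower against that background. The endothelial and lymphocyte lists had 4 and 0 genes tested in both settings and are not compared. Of 13101 genes, 7120 differed, 4690 with the effect in iWAT above that at day 7 and 2430 below. Among the 10984 tested in both settings the numbers were 4198 and 1962. Median-of-ratios scaling shifted the median of all genes by −0.176 (log2) and gave 3322 above and 3321 below, and quantile normalization shifted it by −0.147 and gave 3484 and 3038.

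**Figure D3:**
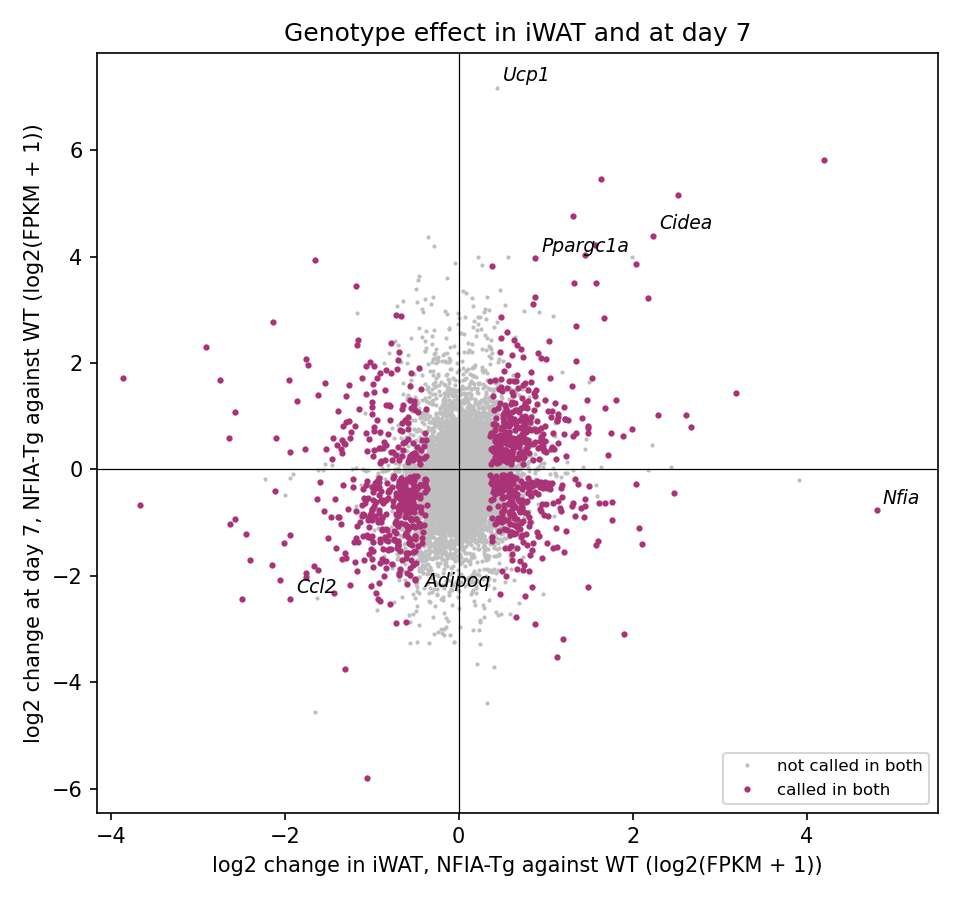
Log2 change of NFIA-Tg against WT in iWAT (x axis) and at day 7 (y axis), on the log2(FPKM + 1) scale, one point per gene measured in both, purple where called in both and grey otherwise, with Nfia, Ucp1, Cidea, Ppargc1a, Adipoq and Ccl2 named. Nfia lies at 4.81 in iWAT and −0.76 at day 7, and Ucp1 at 0.44 and 7.18.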

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

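The splits of the samples and the test on blood were set before their results were seen, and all other tests on Nfia, the unfolded protein response and endothelial markers were chosen after. The first results here are genotype effects that differ between settings, each by a test of the difference. The endothelial markers weighed at the end are an effect in iWAT that was not compared between settings. Bootstrap intervals below resample the genes of a list and not the libraries, so they do not measure the spread between samples.

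Between day 7 and day 0, the genotype effect differed in 9051 genes. Among named genes the effect was higher at day 7, as a log2 difference, in Ucp1 (7.17), Cidea (4.45), Ppargc1a (3.84), Prlr (1.98), Ndufb9 (0.79) and Mrpl13 (0.72). It was lower in Cldn15 (−3.99), Ngfr (−2.82), Il1r1 (−2.68), Adipoq (−2.44), Ccl2 (−2.17), Pparg (−1.75), Nfix (−1.75), Nfia (−1.56), Nfic (−1.04), Oas1a (−0.88) and Rps4x (−0.43). By list, the median difference was higher for thermogenic genes (0.97), glucose uptake and insulin signalling (0.72), the tricarboxylic acid cycle (0.49), oxidative phosphorylation (0.36) and the mitochondrial ribosome (0.22), and lower for preadipocyte and fibroblast markers (−2.38), matrix and fibrosis (−1.60) and mature adipocyte genes (−1.14). None of these lists held with an estimated correlation (adjusted p = 0.329 to 0.537 with an estimated correlation).

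Between iWAT and day 7 it differed in 7120 genes. Among named genes it was higher in iWAT, as a log2 difference, in Nfia (5.56), Adipoq (1.86), Nfix (1.83) and Nfic (1.05) and lower in Ucp1 (−6.74), Cox7a1 (−3.82), Ppargc1a (−3.09), Cidea (−2.16), Cox8b (−1.61) and Nfib (−0.79). By list, the median difference was higher for matrix and fibrosis (1.39), interferon-stimulated genes (1.13), preadipocyte and fibroblast markers (1.09) and proliferation (0.76), and lower for thermogenic genes (−0.84), glucose uptake and insulin signalling (−0.30) and oxidative phosphorylation (−0.0451). None of these held with an estimated correlation (adjusted p = 0.375 to 0.883 with an estimated correlation). The oxidative phosphorylation median is near 0, and its call is relative to the median of all genes of 0.181. That median was 0.00496 under median-of-ratios scaling, and whether the call holds under it was not tested.

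How many genes other splits of the same samples called was counted for each comparison. With 3 samples against 3 there are 10 splits, so no share can be under 0.05. The real split called 1413 genes in iWAT, 7911 at day 0, 10155 at day 7, 10246 for differentiation in WT and 10950 in NFIA-Tg, and the highest of the others called 1, 1, 0, 0 and 0 genes. Each other split mixes the 2 groups compared, so their difference widens the spread within the split groups. Low counts there follow from the design and are no separate evidence. For genotype by differentiation, 1 of 100 drawn splits, the real one with 9051 genes, reached that count (highest other 6929). Exchanging the genotype labels on 1 day only was not among the draws and called 9879 genes, since it measures the sum of both effects. For iWAT against day 7, 2 of 100 splits reached 7120 genes, the other being that exchange (7469 genes). Both shares depend on which splits were drawn. Whether replicates are separate animals or cultures is not stated, so these splits cannot exclude chance differences between animals or cultures.

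Nfia stands against its label at day 7 (log2 change −0.76) and with it in iWAT and at day 0. An exchange of genotype labels in the cultures on both days would put Nfia lower in the libraries labelled NFIA-Tg at day 0 if the transgene is active before induction. In that case the observed log2 change of 0.80 argues against it. The promoter is not given, so an exchange with a transgene silent at day 0 was not tested. An exchange at day 7 alone would move genes with reads in only 1 genotype to the other, but of genes with at most 3 reads in one genotype and at least 20 in the other at day 0, 16 of 21 (76.2%, exact binomial p = 0.0266) were higher in the same genotype at day 7, short of the 90% set to exclude an exchange and over the 50% set for one, and a first version on FPKM, seen before, gave 11 of 15 (73.3%). A further criterion, adopted only after those shares had fallen short, took genes one-sided on both days, and 7 of 7 (100%, exact 95% interval 59 to 100%) kept their side, which argues against the exchange. Transgene reads left uncounted in the cultures would by themselves leave Nfia unchanged, and the log2 change of −0.76 ± 0.05 at day 7 argues against them as the whole cause; together with a change of the endogenous gene, which was not tested, they stay open, although the log2 change below 0 set for them on both days was met at day 7 only.

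Genes of the unfolded protein response, the chaperone and stress programme of the endoplasmic reticulum, were higher at day 7 in the libraries labelled NFIA-Tg, with a list median of 1.57. A difference of these genes already present at day 0 is argued against by the median there of −0.0675 (95% bootstrap interval over genes −0.16 to 0.09). A difference between the cultures that shows only after induction cannot be seen at day 0 and was not tested. Scaling by total reads is argued against by a median of 1.70 under median-of-ratios scaling (1.20 to 2.06). Handling at harvest that raises early-response genes is argued against by their median change at day 7 of −0.19 (−0.48 to 0.12). Culture conditions that leave the early-response genes unchanged were not tested. Stress of the endoplasmic reticulum in thermogenic cells is a hypothesis that the genotype groups leave open, and it was not tested further.

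Endothelial markers were lower in NFIA-Tg iWAT, with a median log2 change of −0.50 and 7 of 16 members called. The list call did not hold with an estimated correlation (adjusted p = 0.370 with an estimated correlation). A larger share of adipocyte RNA would lower the markers of other cell types alike. The endothelial median lay below that of preadipocyte and fibroblast markers by a difference of −0.54 (95% bootstrap interval over genes −0.76 to −0.25). It lay below that of macrophage markers by −0.46 (−0.65 to −0.07). These intervals treat genes as independent, so whether the differences exceed the spread between libraries was not tested. Less blood in the pieces was weighed by a fit with the erythroid level as a covariate. In it, 100% of the 7 called endothelial genes kept more than 50% of their change and 6 were still called. The exception was Egfl7, whose log2 change went from −0.56 to −0.52 with 1 degree of freedom fewer (adjusted p = 0.0756). Only called genes entered this count, and called genes vary little within groups. They were therefore likely to keep their change, and the fit cannot decide whether less blood plays a part. A lower content of endothelial cells in NFIA-Tg iWAT, or lower expression in them, stays open and was not tested.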

How the results depend on the processing

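Limma voom on recovered reads and the fit without 3 culture libraries were chosen after the data were seen, and the other alternatives before. Over 64 list results, 1536 of 1636 alternatives kept direction and side of the threshold, 66 lost the call, 34 gained one and 0 reversed. With camera at an estimated correlation, 28 of the 64 lost the call and 36 stayed the same. Under it no list was called in iWAT, at day 0 or at day 7 (lowest adjusted p = 0.137). With fry, 5 of the 64 lost the call and 16 gained one. Over 325 named-gene results the numbers were 8256 of 8378, 88, 32 and 2. The reversals were in Nfib for genotype by differentiation, not called and positive as reported, at −0.68 with a pseudocount of 0.1 and −0.91 with voom, and the cause was not tested.

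In iWAT the count of called genes was 934 with no filter, 2524 with sample weights, 5141 with all 18 samples in 1 fit, and 617 to 1262 with 1 library left out, where fewer samples enter. A minimum log2 change of 1, which removes small changes by construction, left 345 genes there and 777, 2184, 3061, 4692, 2365 and 2313 at day 0, at day 7, for differentiation in WT and NFIA-Tg, for their contrast and for iWAT against day 7. Other counts moved by less than 1.5 times. Adjusted p of the oxidative phosphorylation list was 0.370 in iWAT and 0.434 at day 7 with an estimated correlation, and at day 0, where it was not called, 0.0333 with only the groups compared and 0.0443 to 0.168 with 1 library left out. For the inflammatory list it was 0.385 and 0.597 in iWAT and at day 7 with an estimated correlation, and in iWAT 0.203 with fry, 0.103 with no filter, 0.0529 with median-of-ratios scaling, 0.0533 with quantile normalization, 0.0635 with all 18 samples and 0.00311 to 0.0849 with 1 library left out. Beyond these, the cause was not tested.

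Replicate numbers did not pair the samples. Of 21 correlations of same-numbered deviations, 3 were over 0.1 (−0.108 to 0.156), and the own number was best in 6 of 21. With the number as a block, 1282, 7822, 10136, 10239, 10927, 9027 and 7097 genes were called in iWAT and in the other comparisons in the order above. It ended the calls of the macrophage (0.0589) and pericyte (0.0531) lists and of Tnfaip2 (0.0604), Irgm2 (0.0556), Igtp (0.0692) and S100a8 (0.0571) in iWAT and of Krt19 (0.0519) for iWAT against day 7, and Nfix passed at day 0 (0.0290), adjusted p in parentheses. Voom called 7961, 10185, 10287, 10953 and 8837 genes in the 5 culture comparisons, and the fit without day 0 NFIA-Tg replicate 3, day 7 NFIA-Tg replicate 1 and day 7 WT replicate 3 called 7285, 9246, 9790, 10261 and 8063. Unknown read depth limits what can be said of low genes in iWAT.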

Other observations

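The 3 gene lists, the single genes and the overlap of day 0 with day 7 below were all chosen after the values had been seen. In the libraries labelled NFIA-Tg, genes of the unfolded protein response rose together at day 7, 27 of 28 higher and 1 lower, with a median log2 change of 1.57. Over the 3 lists alone, camera gave adjusted p = 2.58e-15, and adjusted p = 0.0113 with an estimated correlation (unadjusted p = 0.00752). The fixed lists were adjusted over more lists, so these values cannot be set beside theirs. An adjustment over all lists together was not run. Hspa5, the main chaperone of the endoplasmic reticulum, was 304 ± 8.17 FPKM in WT and 2883 ± 179 in the libraries labelled NFIA-Tg (log2 change 3.24, adjusted p = 2.82e-13). Herpud1, of protein degradation at that organelle, was 27.6 ± 0.991 and 228 ± 19 FPKM, and Sdf2l1 10.9 ± 0.676 and 124 ± 18.9 FPKM (log2 change 3.38). Targets of ATF4, the transcription factor of the integrated stress response, had 18 of 21 higher and 3 lower (median 0.77). Again over the 3 lists alone, adjusted p by camera was 2.31e-07, and 0.0113 with an estimated correlation (unadjusted p = 0.00633). Chac1 was at 11.1 ± 0.327 and 47.3 ± 4.46 FPKM and Asns at 94.4 ± 5.91 and 162 ± 7.28 FPKM. Neither list was called at day 0 (adjusted p = 0.990 and 0.437) or in iWAT (0.605 and 0.838), where 1 of 28 and 2 of 20 genes were higher and 0 and 1 lower. The effect at day 7 exceeded that at day 0 for both lists (medians 1.67 and 0.90). Over the 3 lists alone, adjusted p by camera was 7.72e-15 and 4.28e-06, and 0.0170 with an estimated correlation for each (unadjusted p = 0.00821 and 0.0113).

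All 8 measured genes of the Hoxb cluster, transcription factors that mark position along the body, were lower in the cultures labelled NFIA-Tg on both days, with medians of −1.52 at day 0 and −2.07 at day 7. Over the 3 lists chosen later alone, adjusted p by camera was 1.54e-06 and 0.000165, and 0.0110 and 0.0160 with an estimated correlation (unadjusted p = 0.00366 and 0.0160). These values cannot be set beside those of the fixed lists. Hoxb9 was 26.9 ± 0.669 and 3.03 ± 0.151 FPKM at day 0, and 12.1 ± 0.880 and 0.512 ± 0.0527 FPKM at day 7. In iWAT none of the 8 was called (limma, adjusted p of the list 0.605). As for the other culture results, the transgene and other differences between the cultures cannot be told apart here. Xlr3b was listed at 0 in the 6 culture libraries labelled NFIA-Tg and stood at 7.07 and 4.62 FPKM in WT at day 0 and day 7. Genotype calls at day 0 and day 7 overlapped, with 1374 genes higher and 2821 lower on both days (odds ratios 1.78 and 2.32, 1054 and 2235 genes for independent lists), while 1548 and 864 went in opposite directions.

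In iWAT, Prdx6, a peroxiredoxin that reduces lipid peroxides, was among the largest changes outside the naming rule, with mean FPKM of 118 in WT and 1085 in NFIA-Tg (log2 change 3.19, adjusted p = 4.39e-05; at day 7 1.44). Pigc, an enzyme of glycosylphosphatidylinositol anchor synthesis, was at 6.53 and 28.8 FPKM (log2 change 1.99, adjusted p = 0.000108; at day 7 0.77). Some culture libraries stood apart. Xist, the RNA of the inactive X chromosome, was 1.09 FPKM in day 0 NFIA-Tg replicate 3 and at most 0.0487 in the other culture libraries. The ribosomal precursor Rn45s took 2.1% of reads in day 7 NFIA-Tg replicate 1, 0.756% in day 7 WT replicate 3, 0.735% in day 7 NFIA-Tg replicate 2 and 0.438% in day 7 NFIA-Tg replicate 3, and at most 0.107% in the others.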
